A study of Homo sapiens with 6 samples.

How the data were processed

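RNA-seq was deposited for 6 libraries of HEK293T landing pad lines, 3 labelled PGK and 3 labelled CAG. Per the labels' protocols, cells were scraped from plates below confluence, RNA was taken up in Trizol, and directional libraries were made after polyA selection. The authors deposited whole-number read counts for 20169 Ensembl genes, not normalized and not pooled over replicates. Per the submitters' processing notes, cutadapt 4.6, Bowtie2 2.5.1, HISAT2 2.2.1 and featureCounts 2.0.3 were used with the hg19 genome; the role of each, the annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Without a stated strand setting, reads of a gene and of an antisense partner cannot be told apart, and genes with near-identical copies can lose or share reads; the named genes this touches are marked as uncertain.

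The 6 columns were matched to samples by their labels, with 0 columns left over, and the groups come from the labels. Of the 20169 gene rows, 19346 were paired with a symbol, chromosome and order of neighbours by their Ensembl identifiers in GENCODE 29, and 823 had no symbol and were kept in the tests but not named. GENCODE 29 is built on GRCh38, not on hg19, so it was used only for names, chromosomes, neighbour order, overlaps, and the GC content and length of transcripts, and no coordinates are given. It calls 97.4% of the matched rows protein-coding. No count was found in any library for 3535 rows, and 0 rows named no gene.

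Genes were filtered with edgeR's filterByExpr, counts were scaled by TMM, and the lines were compared with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust fit, two-sided) with Benjamini-Hochberg adjustment over the 13103 genes kept; genes with an adjusted p under 0.05 were called. Fold changes are CAG over PGK, and each standard error is the log2 fold change over the root of its F statistic. Levels are CPM on the TMM-scaled library size, as mean ± SD over 3 libraries. A gene at 0 counts in a line was set against a floor of 3 counts per library, which is 0.126 to 0.140 CPM at these depths, and the difference is given as a lower bound; with 1 to 6 counts the ratio is given with a 95% exact binomial counting interval. Intervals and floors cover counting error only, since reads copied by PCR are not independent molecules. The biological coefficient of variation was 0.0494.

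Before the data were examined, the groups, the tests, the gene lists, the rule for named genes and the other settings to be tried were fixed. Named genes were the 8 with the largest log2 fold change in each direction among called genes with no overlap between lines and a mean of at least 5 CPM in the higher line, the up to 2 called members with the largest change in each list, and PGK1, ACTB, GAPDH and PPP1R12C; other genes were chosen after their values were seen. Some genes that met this rule are not reported here. The 28 lists were the microRNA pathway, deadenylation, 3'UTR-binding proteins, decapping and exonucleolytic decay, nonsense-mediated decay, cleavage and polyadenylation, m6A machinery, transgene silencing and heterochromatin, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, nuclear oxidative phosphorylation, replication-dependent histones, unfolded protein and integrated stress response, interferon-stimulated genes, cholesterol biosynthesis, glycolysis and hypoxia response, p53 targets, G2/M cell cycle, serum and YAP response, HOX genes, clustered protocadherins, numbered zinc finger genes, imprinted genes, neuronal, renal and epithelial, fibroblast and matrix and immune markers, and genes around the AAVS1 site, a site commonly used for insertions that no label names for these lines. The 27 lists with at least 5 tested members, and each chromosome, were set against the other tested genes with limma's camera test (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, each family with its own adjustment. With a correlation estimated from the data, camera called 0 lists, with 3 at an unadjusted p under 0.05 (p53 targets, serum and YAP response, fibroblast and matrix markers) and a smallest adjusted p of 0.214; fry, which asks whether a list moves at all and does not compare it with other genes, called 19 lists. Windows of 50 neighbouring genes were planned; the median of 0.25 that defines a shifted window and the joining of windows into runs were chosen after the data were seen. Medians of lists and runs were the same with genes at 0 counts at their bound.

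The alternatives were no low-count filter, a stricter filter of 1 CPM in 3 libraries, RLE size factors, library size only, DESeq2 1.42.0, limma-voom, a test against a fold of 1.5, a replicate block, another prior count, an estimated correlation, fry, and leaving out each library in turn. The analysis was tested on simulated counts for the 13103 genes at the real depths, where it recovered 52% of genes changed by 1.25-fold, 82% at 1.5-fold, 90% at 2-fold and 98% at 4-fold; 11 of 172 calls (6.40%) were genes that had not been changed. Only 50 genes were changed at each fold, whereas 62.0% of tested genes were called in the real data. The recovered and false shares therefore need not hold for the real calls. The analysis also recovered 5 of 5 shifted windows and called 0 other windows and 0 lists. Simulated counts were drawn for each gene on its own, with no correlation between genes. The simulation therefore cannot show how often the list and window tests call falsely in real libraries. In splits of the real libraries that mix the lines, camera at the preset correlation called 1 to 9 lists. Each side of such a split held more libraries of one line, so part of the line difference remained. These list calls therefore need not be false, and the splits do not give a rate of false calls. The landing pad and its reporter are not among the genes counted and were not analysed here.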

Results

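Gene expression was measured by RNA-seq of polyadenylated RNA in HEK293T cells, a human embryonic kidney line that carries a viral large T antigen. The cells held a landing pad, a docking site in the genome into which a reporter gene can be inserted, driven by either the PGK or the CAG promoter. PGK is the promoter of the glycolytic gene PGK1, and CAG is a strong composite promoter with parts of a viral enhancer and of an actin promoter. Each group held 3 libraries, with total counts of 21896246, 22528774 and 22889708 for PGK and 22450538, 23315828 and 23442542 for CAG. A count was found for 14952 to 14980 genes in the PGK libraries and for 15298 to 15360 genes in the CAG libraries. The series concerns the effect of 3'UTRs on expression, and the single comparison in its design asks how the transcriptomes of these host lines differ. The labels tell apart no more than 1 line per promoter, so promoter and clone differ together in every value given here. They also do not say that the libraries of a line came from separate cultures, so p-values measure the spread between these samples, which may be technical.

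The CAG line expressed a set of genes that were at or near 0 counts in the PGK line. GTSF1 (ENSG00000170627, chromosome 12), which acts in the piRNA pathway of germ cells, had 0 counts in all 3 PGK libraries and 44.6 ± 2.29 CPM in CAG (SD, n = 3), at least 329-fold higher. MAGEA1 (ENSG00000198681, chromosome X), a cancer-testis antigen, rose from 2 counts in all, both in PGK replicate 3, to 119.6 ± 1.28 CPM. The ratio was 3981 with a counting interval of 1102 to 32874. GABRA3, a subunit of the GABA receptor, was at least 61.0-fold higher, at 8.26 ± 0.226 CPM against 0 counts. MKRN3, an imprinted gene expressed from the paternal copy, had 3 counts in PGK and 11.1 ± 0.711 CPM in CAG, a ratio of 248 with a counting interval of 84.4 to 1203. The microRNA host transcript MIR3667HG also had 3 counts in PGK, against 20.1 ± 1.53 CPM, a ratio of 446 with an interval of 152 to 2163. LRRC61 had 1 count in PGK and 31.3 ± 0.862 CPM in CAG, a ratio of 2079 with an interval of 373 to 82170. ZBED10P had 0 counts in PGK and 24.3 ± 1.96 CPM in CAG, at least 179-fold higher. This pair overlaps on the same strand, and LRRC61 also overlaps ACTR3C on the other strand, so how their reads divide is uncertain. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of these 7 genes ran from 4.1e-20 for MAGEA1 to 8.7e-13 for GABRA3.

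Other genes were expressed in the PGK line and nearly silent in the CAG line. NEFM (ENSG00000104722, chromosome 8), a neurofilament of neurons, fell from 18.8 ± 1.23 CPM in PGK to 0.0853 ± 0.0729 in CAG (SD, n = 3), a PGK to CAG ratio of 219 with a counting interval of 100 to 598. CAG replicate 2 held 4 of its 6 counts in CAG. SFRP2, a secreted Wnt antagonist with 4 counts in CAG, had a PGK to CAG ratio of 178 (counting interval 69.2 to 655). FLRT2, a cell adhesion gene with 6 counts in CAG, had a ratio of 70.6 (counting interval 32.2 to 194). AFF2, the gene behind fragile XE syndrome, changed by -6.48 (SE 0.18) on the log2 scale, WDR72, a gene of enamel formation, by -5.58 (SE 0.15), and TRIM58, a ubiquitin ligase, by -5.49 (SE 0.20). LTBR, the lymphotoxin beta receptor, had 5.04 ± 0.294 CPM in PGK and 0 counts in all CAG libraries, at least 39.2-fold lower. LTBR overlaps SCNN1A on the other strand, and since the strand setting of the counting is not given in the sources used here, its level is uncertain. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of these 7 genes lay between 1.05e-15 for WDR72 and 1.8e-11 for LTBR.

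**Figure D1:**
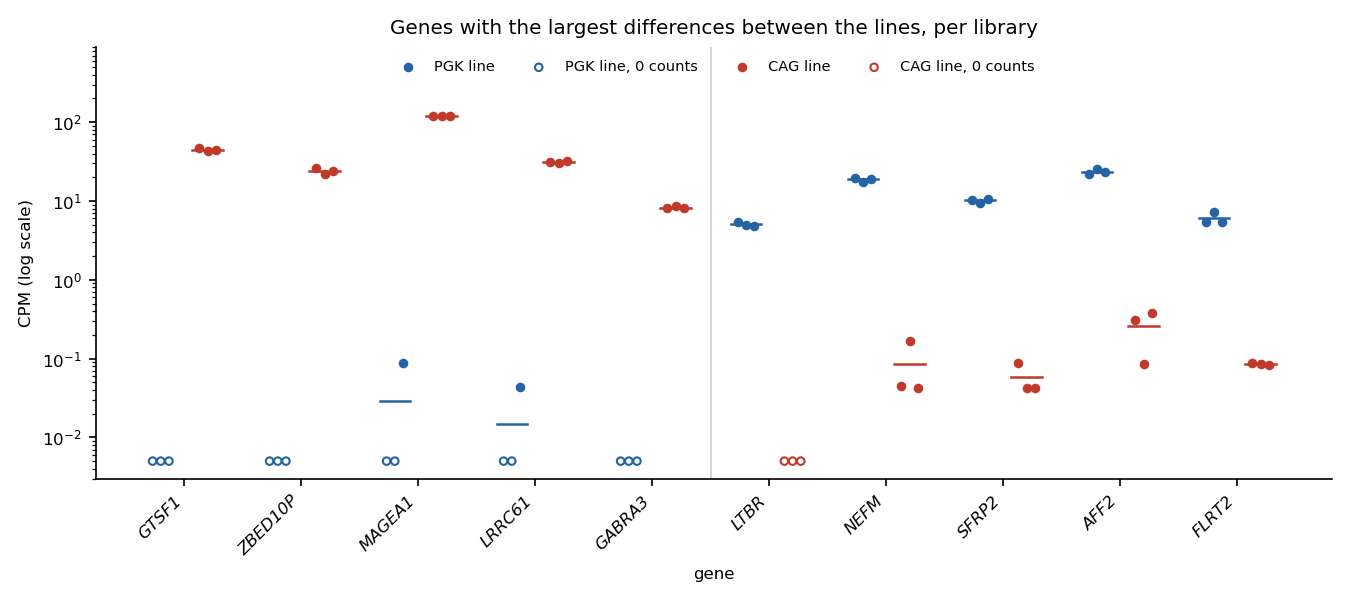
CPM (log scale) of the 5 genes with the largest log2 fold change in each direction among called genes with no overlap between lines and a mean of at least 5 CPM in the higher line, where each point is 1 library and each short line the mean of the 3 libraries of a line; open points, placed low on the axis, are libraries with 0 counts. GTSF1, ZBED10P and GABRA3 had 0 counts in every PGK library, LTBR had 0 counts in every CAG library, and the points of the lines do not overlap for any of the 10 genes.

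Beyond these genes, differences were spread over the transcriptome and mostly small. Of 13103 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 8125 (62.0%), of which 4139 were higher and 3986 lower in CAG. Scaled by library size only, in place of TMM, 4491 were higher and 3509 lower, or 56.1% higher. Of the calls with TMM, 751 were at least 2-fold higher and 378 at least 2-fold lower, while 5463 differed by less than 1.5-fold. At least 8-fold differences were found for 85 higher and 51 lower genes, or 84 and 50 with genes at 0 counts set to their bound. The 3 libraries of one line all lay above the 3 of the other for 8584 tested genes (65.5%), where chance gives 10%. Tested against a fold of 1.5 in place of no change, 954 genes were higher and 558 lower. Libraries of a line were alike, with Pearson correlations of log2 CPM across genes of 0.995 to 0.997, against 0.958 to 0.960 between lines. The first principal component, which parted the lines, held 87.6% of the variance. No pair of libraries of a line was alike within sampling noise, since the chi-square of their counts per degree of freedom was at least 3.41, against at least 51.04 between lines.

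The endogenous counterparts of the promoters and the housekeeping genes differed little. PGK1, the glycolytic phosphoglycerate kinase, was higher in CAG at 555 ± 6.60 CPM against 471 ± 3.03 (SD, n = 3), a log2 fold change of 0.24 (SE 0.04). Its adjusted p was 1.1e-04 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. PGK1 overlaps ATP7A and PGAM4, so its level is uncertain. The median log2 fold change of its window of neighbouring genes was 0.21, so the difference was not particular to PGK1. ACTB, which encodes beta-actin, was at 2495 ± 76.6 CPM in CAG and 2304 ± 73.0 in PGK, a log2 fold change of 0.11 (SE 0.05). Its adjusted p was 0.0411 in the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The ACTB call was lost with no low-count filter, with RLE size factors, with DESeq2 and without PGK replicate 1, PGK replicate 2, CAG replicate 1 or CAG replicate 3. GAPDH, a glycolytic enzyme, had a log2 fold change of -0.08 (SE 0.05) and did not pass. Its adjusted p was 0.162 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 0.0412 without PGK replicate 1, in a range of 0.0412 to 0.502 over the alternatives. PPP1R12C, the gene that holds the AAVS1 site commonly used for insertions, was higher by 0.42 (SE 0.08) on the log2 scale. This lay below the median of 0.62 of its window of neighbouring genes. Where the landing pad lies is not given in the sources used here.

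Called genes of microRNA function and mRNA turnover, the machinery that reads 3'UTRs, went in both directions. Of all tested genes 62.0% were called, so calls among members do not by themselves set these lists apart. In the microRNA pathway, 3 of 18 tested genes were higher (3 adjusted over the list alone) and 5 lower (4 adjusted over the list alone). AGO3 rose by 0.61 (SE 0.06) and AGO2, the slicing Argonaute, changed by -0.38 (SE 0.09). Among 3'UTR-binding proteins 15 of 40 were higher and 10 lower, the same counts as adjusted over the list alone. SAMD4A, a repressor of translation, changed by -1.47 (SE 0.10) and STAU2, which binds double-stranded RNA, by 0.79 (SE 0.06). Of 22 deadenylation genes 6 were higher and 8 lower (6 and 9 adjusted over the list alone). The deadenylase subunit CNOT3 rose by 0.80 (SE 0.05) and TOB1, which recruits deadenylases, changed by -0.56 (SE 0.07). Decapping and exonucleolytic decay had 12 higher and 7 lower of 33 (12 and 6 adjusted over the list alone), among them the exosome subunits EXOSC8 at 0.63 (SE 0.05) and EXOSC4 at -0.93 (SE 0.10). Nonsense-mediated decay had 8 higher and 4 lower of 17, the same adjusted over the list alone, led by UPF3A at 0.69 (SE 0.09) and UPF2 at 0.43 (SE 0.06). Of 22 cleavage and polyadenylation genes, 5 were higher and 7 lower (5 and 6 adjusted over the list alone), with the phosphatase SSU72 at -0.91 (SE 0.06) and the scaffold SYMPK at 0.51 (SE 0.05). In the m6A machinery 5 of 17 were higher and 5 lower, the same adjusted over the list alone, with the methyltransferase component ZC3H13 at 0.84 (SE 0.05) and the reader IGF2BP2 at -0.71 (SE 0.05). None of these 7 lists stood apart from the other tested genes in limma's camera test, with adjusted p from 0.580 for nonsense-mediated decay to 0.959. CNOT3, EXOSC8, SSU72 and IGF2BP2 overlap a gene on the other strand, so their values are uncertain. Of the 14 genes named here 10, and of the 100 called genes of these lists 45, lay in windows of neighbouring genes that shifted the same way, as described below. For comparison, 2948 of all 8125 called genes lay in shifted windows, whichever way the gene itself went. Whether the share in these lists differs was not tested. The median of the m6A list was -0.02 while its mean was 0.04.

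Targets of p53 and genes of the serum and YAP response were lower in the CAG line. Of 22 tested p53 targets 17 were lower and 1 higher, also adjusted over the list alone, with a median log2 fold change of -0.42. PLK2, a stress-induced kinase, fell by 1.47 (SE 0.13) and PHLDA3, an inhibitor of AKT signalling, fell by 1.45 (SE 0.09). CDKN1A, the cell cycle inhibitor p21 and a gene chosen after its value was seen, changed by -1.33. Of 23 serum and YAP response genes 17 were lower and 1 higher, also adjusted over the list alone, with a median of -0.44. The YAP target CCN2 fell by 1.90 (SE 0.13). ACTA2, a smooth muscle actin that overlaps FAS and STAMBPL1 on the other strand and is uncertain, fell by 2.19 (SE 0.16). Both lists had an adjusted p of 3.2e-04 in limma's camera test with a preset correlation, and an adjusted p of 0.214 with an estimated correlation.

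Genes of the ribosome, of respiration and of mitosis were lower by smaller amounts. Among 78 cytosolic ribosomal proteins 39 were lower and 13 higher (40 and 13 adjusted over the list alone), with a median of -0.26. RPL11, which also binds MDM2, fell by 0.95 (SE 0.06) from 1067 ± 98.9 CPM to 552.6 ± 20.8 (SD, n = 3). RPL35A fell by 0.92 (SE 0.09), and it overlaps IQCG on the other strand. The windows of neighbouring genes around RPL11 and RPL35A also shifted lower, with medians of -0.64 and -0.63. Many ribosomal protein genes have near-identical pseudogenes, so their values are uncertain. Of 64 nuclear genes of oxidative phosphorylation 32 were lower and 7 higher, the same adjusted over the list alone, with a median of -0.19. NDUFB5 of the NADH dehydrogenase complex changed by -0.85 (SE 0.06) and the succinate dehydrogenase subunit SDHB by -0.82 (SE 0.05). Of 30 G2/M genes 17 were lower and 4 higher (19 and 4 adjusted over the list alone), with a median of -0.14. The securin gene PTTG1 changed by -0.67 (SE 0.06) and the mitotic kinesin CENPE by 0.58 (SE 0.12). Both lay in windows of neighbouring genes that shifted the same way, with medians of -0.44 for PTTG1 and 0.54 for CENPE. The camera test with a preset correlation gave adjusted p of 0.00198 for ribosomal proteins, 0.00248 for oxidative phosphorylation and 0.0464 for G2/M. The adjusted p with an estimated correlation was 0.868, 0.848 and 0.624. The ribosomal call was also lost with fry, with an adjusted p of 0.0571 in a range of 3.2e-07 to 0.868 over the alternatives. The G2/M call was lost with the stricter low-count filter and without PGK replicate 2, PGK replicate 3, CAG replicate 1 or CAG replicate 3, with an adjusted p of up to 0.0877 in these 5 fits and a range of 0.0148 to 0.624 over all alternatives. It was also lost once the median of each gene's chromosome neighbourhood was subtracted, with an adjusted p of 0.293.

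Stress response and cholesterol synthesis genes were higher in the CAG line. Of 28 genes of the unfolded protein and integrated stress response 20 were higher and 3 lower, the same adjusted over the list alone, with a median of 0.24. SLC7A11, the cystine transporter, rose from 6.66 ± 0.133 to 59.5 ± 2.19 CPM (SD, n = 3), a log2 fold change of 3.16 (SE 0.07), and CHAC1, which degrades glutathione, rose by 1.06 (SE 0.18). ATF4, the transcription factor that drives both, changed by 0.50 while its target DDIT3 changed by -0.44. This pair was chosen after the values were seen. Of 24 cholesterol biosynthesis genes 16 were higher and 5 lower, the same adjusted over the list alone, with a median of 0.32. The sterol oxidase MSMO1 rose by 1.22 (SE 0.06) and the isomerase IDI1 by 0.83 (SE 0.05). Their windows of neighbouring genes also shifted higher, with medians of 0.40 for MSMO1 and 0.52 for IDI1. The camera test with a preset correlation gave adjusted p of 0.00198 for the stress response and 0.00655 for cholesterol synthesis. The adjusted p with an estimated correlation was 0.382 and 0.389.

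HOX genes, which pattern the body axis, numbered zinc finger genes and matrix genes were also higher. Of 36 HOX genes 21 were higher and 3 lower, the same adjusted over the list alone, with a median of 0.32. HOXB6 rose by 0.88 (SE 0.05) and HOXB8 by 0.87 (SE 0.08). HOXB6 overlaps HOXB3 and HOXB8 overlaps HOXB7 on the same strand, so both are uncertain. Of 418 numbered zinc finger genes 222 were higher and 97 lower (223 and 99 adjusted over the list alone), with a median of 0.25. ZNF334 had 1 count in PGK and 4.38 ± 0.463 CPM in CAG (SD, n = 3), a ratio of 292 with a counting interval of 52.0 to 11567. ZNF544 had 4 counts in PGK, 3 of them in PGK replicate 2, and 9.95 ± 0.408 CPM in CAG, a ratio of 165 with an interval of 64.3 to 609. The 197 zinc finger genes tested on chromosome 19 had a median of 0.58, with 134 higher and 42 lower, against a median of 0.08 for the 221 elsewhere, with 88 higher and 55 lower. Within the higher run of neighbouring genes on chromosome 19 described below, zinc finger genes had a median of 0.84, with 129 of 140 higher, and the other genes one of 0.44, with 247 of 342 higher. Of 15 fibroblast and matrix markers 11 were higher and 2 lower, the same adjusted over the list alone, with a median of 0.47. The collagen COL3A1 rose by 2.02 (SE 0.15) and the proteoglycan LUM by 1.91 (SE 0.32). LUM was low in both lines, at 0.271 CPM in PGK and 1.03 in CAG. Among genes around the AAVS1 site 12 of 17 were higher and 1 lower, the same adjusted over the list alone, with a median of 0.37. The cardiac troponin TNNI3 rose by 2.35 (SE 0.18). The synaptotagmin SYT5 was lower, with 2 counts in CAG, both in CAG replicate 2, and a PGK to CAG ratio of 52.1 (counting interval 14.0 to 436). In the camera test with a preset correlation the adjusted p was 0.00254 for HOX genes, 0.00196 for zinc finger genes, 0.00299 for matrix markers and 0.0218 for the AAVS1 list. The adjusted p with an estimated correlation was 0.525, 0.572, 0.214 and 0.818. The AAVS1 call was lost without CAG replicate 1, 2 or 3, with adjusted p of 0.0950, 0.0564 and 0.0626. It reversed once the median of each gene's chromosome neighbourhood was subtracted, with an adjusted p of 0.0236. Over all alternatives its adjusted p ran from 0.00333 to 0.818. The zinc finger call was lost with the same subtraction, with an adjusted p of 0.139, but not when zinc finger genes were left out of the neighbourhood median, with an adjusted p of 0.0235. It was also lost for the genes not on chromosome 19, with an adjusted p of 0.257, in a range of 5.3e-04 to 0.572 over the alternatives.

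**Figure D2:**
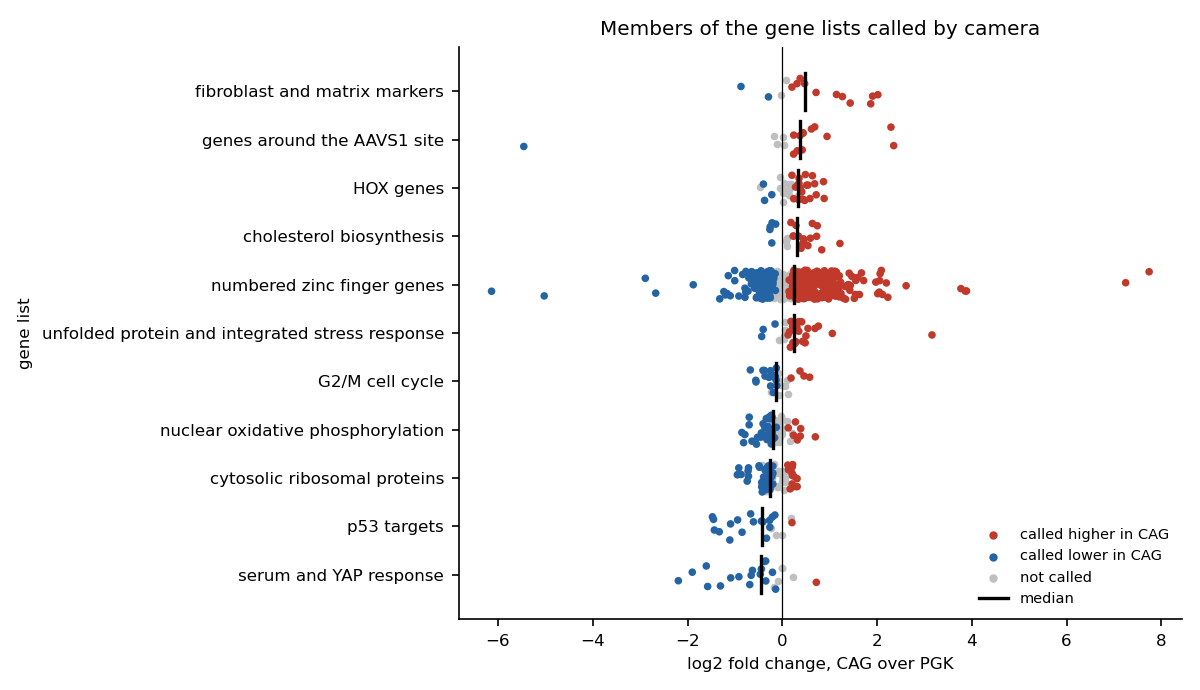
Log2 fold change (CAG over PGK) of each tested member of the 11 gene lists called by limma's camera test with a preset correlation, coloured by whether edgeR called the gene higher, lower or neither, with a black line at the median of the list. The medians run from -0.44 for the serum and YAP response to 0.47 for fibroblast and matrix markers, and members on both sides of 0 are found in every list.

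The remaining lists did not stand apart as lists, though several held genes that differed strongly. NDRG1, a gene induced by hypoxia, fell by 2.87 (SE 0.05) from 321 ± 4.64 to 43.8 ± 0.398 CPM (SD, n = 3). SLC2A3, a glucose transporter with the near-identical copy SLC2A14 and therefore uncertain, was higher by 2.41 (SE 0.39). SLC2A3 was low in both lines, at 0.259 CPM in PGK and 1.39 in CAG, and PGK replicate 3 held 1 of its 17 PGK counts. In this glycolysis and hypoxia list 16 of 29 were lower and 8 higher. The antiviral gene OAS3 was higher by 2.32 (SE 0.30) and IFITM1, which overlaps IFITM2 and is uncertain, fell by 1.99 (SE 0.20). OAS3 was low in both lines, at 0.272 CPM in PGK and 1.37 in CAG. Of 24 interferon-stimulated genes 8 were higher and 7 lower. Of 27 genes of transgene silencing and heterochromatin 12 were higher and 4 lower (12 and 6 adjusted over the list alone). The heterochromatin protein CBX5 rose by 0.70 (SE 0.05), and the histone methyltransferase SUV39H2, which overlaps DCLRE1C on the other strand and is uncertain, by 0.78 (SE 0.06). The list median was -0.02 while its mean was 0.12. Of 16 imprinted genes 8 were higher and 3 lower, with MKRN3 above and DIRAS3, a growth suppressor, at 1.77 (SE 0.37). DIRAS3 was low in both lines, at 0.254 CPM in PGK and 0.891 in CAG. Replication-dependent histones had 1 higher and 2 lower of 11 (1 and 1 adjusted over the list alone), with H2BC11 at 0.77 (SE 0.17) and H2AC6 at -0.55 (SE 0.15). Of the 13 mRNAs encoded by mitochondria 1 was higher and 0 lower by edgeR; this was MT-CYB, the cytochrome b gene, at 0.20 (SE 0.06), a call lost without CAG replicate 2. Of 4 tested clustered protocadherins, too few for the list test, PCDHGC3 was lower at -1.23 (SE 0.09) and PCDHGC4 higher at 0.74 (SE 0.27). Both overlap other genes of the cluster on the same strand and are uncertain. The PCDHGC4 call was lost with DESeq2 and without PGK replicate 1, PGK replicate 3, CAG replicate 1 or CAG replicate 2. Where not given, counts adjusted over the list alone were the same in these lists. The camera test gave adjusted p of 0.0659 for glycolysis and hypoxia, 0.947 for interferon, 0.642 for silencing, 0.136 for imprinted genes, 0.936 for histones and 0.935 for mitochondrial mRNAs.

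Some markers of epithelial, neuronal and immune cells were also called different between the lines, as were 62.0% of all tested genes. EPCAM, an epithelial adhesion gene, had 2 counts in PGK, both in PGK replicate 3, and 1.11 ± 0.167 CPM in CAG (SD, n = 3). The ratio was 37.1 with a counting interval of 9.93 to 312. The protease inhibitor SPINT2 rose from 5.84 ± 0.635 to 36.3 ± 1.11 CPM, though it overlaps PPP1R14A on the other strand and is uncertain. Of 10 renal and epithelial markers 5 were higher and 2 lower, the same adjusted over the list alone. Of 12 neuronal markers 4 were higher and 5 lower, the same adjusted over the list alone. NEFM fell as given above, while MAP2, a neuronal microtubule protein, had 3 counts in PGK and 0.758 ± 0.0881 CPM in CAG, a ratio of 16.8 with an interval of 5.44 to 84.0. Of 5 immune markers 2 were higher and 1 lower (2 and 2 adjusted over the list alone). LCP1, an actin-bundling protein of leukocytes, rose by 1.69 (SE 0.27) and CD8A, a co-receptor of T cells, by 1.02 (SE 0.25). Both were low, at 0.465 and 0.661 CPM in PGK and 1.51 and 1.34 in CAG. None of these lists passed the camera test, with adjusted p of 0.140 for renal and epithelial, 0.935 for neuronal and 0.821 for immune markers. The neuronal median of 0.16 and mean of -0.06 differed in sign.

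Neighbouring genes differed together along stretches of chromosomes. In windows of 50 consecutive tested genes, ordered by their positions in GENCODE 29 (GRCh38), 48 of 262 windows were shifted higher and 26 lower in CAG, each with a median log2 fold change of at least 0.25 in size and a called camera test. With an estimated correlation camera called 0 of 262 windows, with 58 at an unadjusted p under 0.05. The shifted windows held 3520 genes, or 27.3% of those placed, on 14 chromosomes, as 15 runs of adjoining windows and 9 single windows. On chromosome 13 the 180 tested genes from HMGB1 to CHAMP1 had a median of 0.57, and 90.6% of them had a positive log2 fold change. Most of chromosome 4 was higher, with medians of 0.50 from ZNF721 to TBC1D19 (100 genes) and 0.47 from KIT to FRG1 (327 genes). On chromosome 3 the 400 genes from TRNT1 to DZIP3 had a median of 0.41 and the 78 genes from PARL to LMLN at the other end a median of -0.65. Chromosome 19 also held both directions, with a median of -0.41 over the 400 genes from MIER2 to BORCS8 and 0.52 over the 482 genes from GPATCH1 to MZF1. On chromosome 1 the 250 genes from SAMD11 to SMPDL3B, the stretch that holds RPL11 and SDHB, had a median of -0.59.

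Taken as whole sets, 7 of 23 chromosomes were called in limma's camera test with a preset correlation. Splits of the 6 libraries that mix the lines gave 5 to 8 called chromosomes in this test. Each side of such a split held more libraries of one line, so part of the line difference remained. The splits therefore cannot show how often the test calls chromosomes falsely. The chromosome calls alone do not show that whole chromosomes differed. Every run of shifted windows covered only a part of its chromosome, and those of chromosomes 5 and 8 lay at an end. Chromosomes 3, 4, 13, 15 and X were called higher and chromosomes 5 and 8 lower, with medians of 0.22, 0.45, 0.51, 0.18 and 0.19 and of -0.15 and -0.13. On chromosome 4, 372 of 477 tested genes were higher and 32 lower, and on chromosome 13, 175 of 230 were higher and 21 lower. The adjusted p in the camera test with a preset correlation ran from 1.1e-16 for chromosome 4 to 0.0116 for chromosome 8, and with an estimated correlation from 0.124 for chromosomes 4, 15 and X to 0.170 for chromosomes 3 and 8. With an estimated correlation limma's camera called 0 of 23 chromosomes, with 6 at an unadjusted p under 0.05. The fry test, which does not compare a chromosome with the others, called 17 chromosomes.

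**Figure D3:**
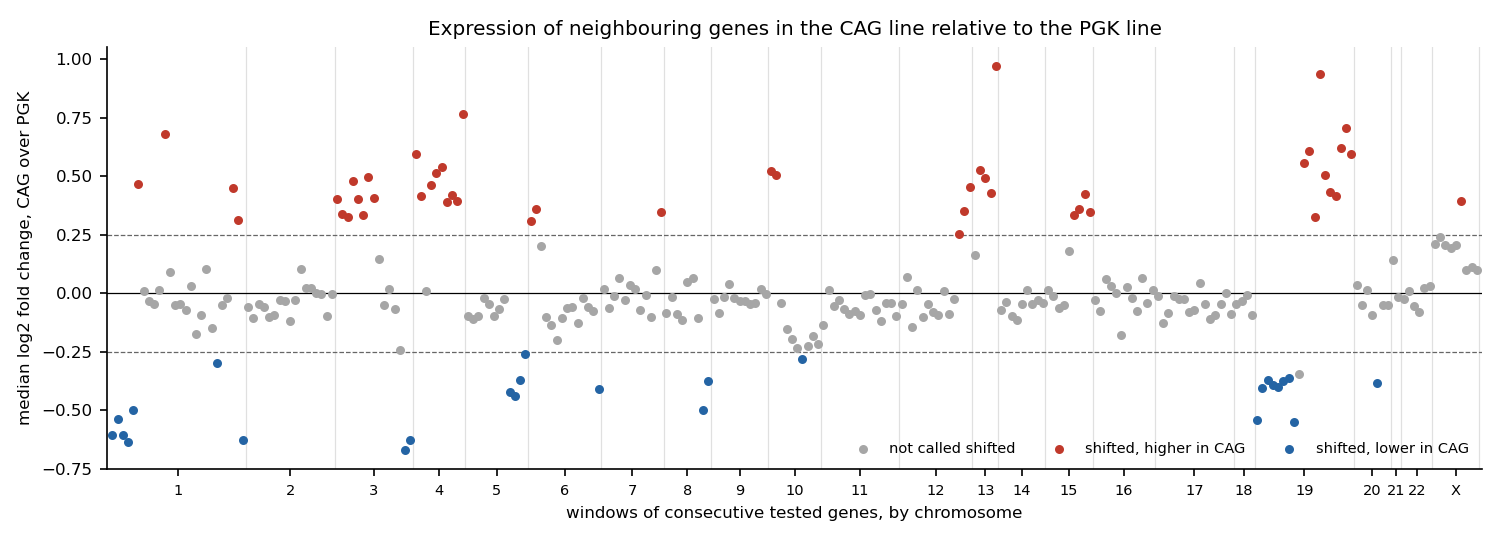
Median log2 fold change (CAG over PGK) of windows of consecutive tested genes, ordered along chromosomes 1 to 22 and X, where each point is 1 window, red and blue points are windows shifted higher and lower in CAG, and dashed lines mark medians of 0.25 and -0.25. Long runs of red points lie on chromosomes 3, 4, 13, 15 and 19 and of blue points at the starts of chromosomes 1 and 19; 1 grey window beyond the line, at -0.34, did not pass the camera test.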

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

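The larger and smaller windows, the subtraction of window medians and of the medians of neighbours outside the list, the zinc finger subset and the other on and off threshold were chosen after the data were seen. Of the 8125 calls, 8057 kept their direction and call with RLE size factors, 8022 with limma-voom, 7648 with library size only and 7283 with DESeq2, and 0 changed sign in any of these fits. Leaving out each library in turn gave 3823 to 4086 higher and 3503 to 3956 lower genes, 9 to 11 lists, 7 to 8 chromosomes and 72 to 75 windows. Tested against a fold of 1.5, 954 genes were higher and 558 lower, since that test asks for a larger change; 1512 of the 8125 calls were kept. With an estimated correlation camera called 0 lists (3 at an unadjusted p under 0.05), 0 chromosomes (6) and 0 windows (58), and fry called 19 lists and 17 chromosomes; the cause was not tested. After window medians were subtracted, the list of genes around the AAVS1 site reversed, with an adjusted p of 0.0236 (0.00333 with its own members left out of the medians, range over its alternatives 0.00333 to 0.818), and all 17 of its tested members lie in shifted windows. Over the 500 most variable genes the first component held 95.6% of the variance. At most 10 counts against at least 100 gave 17 genes on in CAG and 8 on in PGK. Among uncalled lists, glycolysis and hypoxia, imprinted genes and renal and epithelial markers were called in some alternative besides fry, as was chromosome 10. No named gene changed sign; ACTB, PCDHGC4 and MT-CYB lost their calls in 13 fits together, and GAPDH gained 1. ACTB log2 fold change had adjusted p of 0.00711 to 0.158 over its alternatives. Whether the replicate numbers pair the samples is not settled. Deviations from the line means correlated at 0.108, 0.103 and 0.0131 for the same number, so not every value was above 0.1. Between the lines, each library still correlated best with its own number, a hint from the data and not from the design. The replicate block gave 4461 higher and 4400 lower genes, 11 lists and 7 chromosomes. Depth limits genes near the floor: 9 tested genes had 0 counts in every PGK library and 4 in every CAG library, where only a bound can be given.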

Other observations

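The rule for genes on in one line and off in the other, the test of promoter silencing, the comparison with windows reaching the threshold by chance, the test of each list against its neighbours and the genes SP110, SP140L, PARP9, DTX3L, MAGEA3 and MAGEA6 were chosen after the data were seen, as were the patterns themselves.

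With a rule of at most 3 counts in each library of one line and at least 30 in each of the other, 26 genes were on in CAG only and 10 on in PGK only, spread over 18 chromosomes. Besides the genes already named, those on in CAG included LIPE, the hormone-sensitive lipase, at 3.40 ± 0.184 CPM (SD, n = 3) against 0 counts, and SLC7A3, a transporter of cationic amino acids, at 4.66 ± 0.367 against 0.0300 ± 0.0519 CPM. Those on in PGK included PSMD5, a chaperone of proteasome assembly, at 4.63 ± 0.181 against 0.0141 ± 0.0245 CPM in CAG, and the cadherin CDH11 at 4.06 ± 0.699 against 0.0843 ± 0.0730. PARP9 and DTX3L, an interferon-inducible pair that shares a promoter, had 1 and 3 counts in PGK and 167 and 203 in CAG. The neighbours SP140L, with 0 and 188 counts, and SP110, with 12 and 139, both of a family of nuclear body proteins, went the same way. MAGEA6, a cancer-testis antigen like MAGEA1, was at 99.3 ± 1.82 CPM in CAG against 0.848 ± 0.360 in PGK, while MAGEA3 was at 101.4 ± 3.88 in CAG and 97.8 ± 4.22 in PGK; the pair are near-identical copies, so how their reads divide is uncertain. Genes on the X chromosome made up 3.50% of tested genes, and 11 of 85 genes called at least 8-fold higher (12.9%) and 6 of 51 called at least 8-fold lower (11.8%).

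For the genes on in one line and off in the other, reads shared with near-identical copies were searched for among the longest transcripts of the table's genes, and 0 of 36 had a copy with 95% identity over 50% of its length (upper limit 9.74%), which argues against that explanation. Loss of a longer chromosome stretch in the silent line is argued against by the next tested neighbours, since 13.9% of the genes (5 of 36, 95% exact interval 4.67 to 29.5%) had one at least 4-fold lower in the silent line; a loss that ends before the next tested gene stays open. Among these 5 genes, PARP9 and DTX3L are each other's neighbours, as are LRRC61 and ZBED10P, so each pair counts once each way. The interval takes them as independent. Silencing at the promoter may also be at work, but genes starting within 1 kb on the other strand were lower in the silent line in 2 of 3 cases, in which PARP9 and DTX3L count once each way, against 32 of 69 other next neighbours (one-sided Fisher's exact p = 0.458), too few to decide. DNA methylation was not analysed here. A difference between clones that arose before or during their isolation, and the promoter itself, stay among the open explanations, as untested.

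For the runs of neighbouring genes, the arrangement along chromosomes is not what a chance order of genes gives, since in 1000 random orders at most 3 windows had a median of at least 0.25 in size, against 75 in the real order. A trend with GC content and transcript length, fitted to the 98.6% of tested genes with values, explained 0.693% of the variance of log2 fold change, and 90.5% of the shifted windows (67 of 74, 95% exact interval 81.5 to 96.1%) kept their median past 0.25 once it was removed, which argues against that trend as the whole cause but leaves the other windows open. A different copy number of chromosome segments in the lines is a candidate explanation, as HEK293T is aneuploid; in 98.6% of shifted windows (73 of 74) both the lower and the higher expressed genes moved with the window, but so they did in 93.4% of windows that reached the threshold by chance (156 of 167), so this test does not decide it. Copy number and a regional difference in chromatin therefore cannot be told apart here, and no DNA data were analysed.

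For the gene lists, 72.7% of the called lists (8 of 11) were still called in the same direction after the median of each gene's window was subtracted, so different copy number of segments may account for part of them. With the median of neighbours outside the list subtracted in its place, the median of the members was 0.37 (95% interval 0.19 to 0.48, genes taken as independent) for HOX genes, -0.49 (-0.85 to -0.26) for p53 targets, -0.51 (-0.89 to -0.11) for the serum and YAP response, 0.28 (0.16 to 0.43) for cholesterol, 0.21 (0.08 to 0.35) for the stress response, -0.23 (-0.28 to -0.19) for ribosomal proteins and -0.17 (-0.20 to -0.13) for oxidative phosphorylation, and these 7 lists stayed called at the preset correlation (at an estimated one no list was called even before, with adjusted p of 0.214 to 0.868 for these), which argues against segments that span their neighbours as the whole cause; so does it for matrix markers, which stayed called after both subtractions, since their neighbours had a median of -0.00185 (-0.05 to 0.02) against 0.47 (0.08 to 1.43) for the list, though the median of members less neighbours was 0.25 (-0.04 to 1.71). It stays open for G2/M, whose median went from -0.14 (-0.25 to -0.08) to -0.048 (-0.16 to 0.04), for zinc finger genes, which went from 0.25 (0.17 to 0.34) to 0.10 (0.08 to 0.14) and lost their call with only 1 of the subtractions, and for the AAVS1 list, which went from 0.37 (0.03 to 0.61) to -0.46 (-0.81 to -0.21), below its neighbours; segments shorter than a window stay open for all. The 10 splits of the 6 libraries are too few for a share under 0.05: the real split gave 4139 higher and 3986 lower genes and the highest other split 0 by edgeR's quasi-likelihood test, with 14 to 147 genes at an unadjusted p under 0.05 in the others, so 1 split, the real one, was as large. Camera with a preset correlation called 11 lists in the real split and 1 to 9 in the others, so again 1 split was as large. It called 7 chromosomes in the real split and 5 to 8 in the others, where 5 of the 10 splits were as large. Each side of the other splits held more libraries of one line, so part of the line difference remained. The rest widened the spread within each side, which keeps edgeR's count low. Camera at a preset correlation of 0.01 thus called sets where edgeR called 0 genes, but these need not be false calls.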
